A study of Mus musculus with 2 samples.

How the data were processed

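Total RNA of mouse primary T cells was hybridised as biotin-labelled target to Affymetrix 3′ expression arrays, 1 array for cells stimulated with antibodies against CD3 and CD28 and 1 array for cells that also received triptolide at 50 ng/ml. Per the labels' protocols, purified cells were kept in culture for 18 h. The length of the triptolide exposure is not given in the sources used here, nor is the number of animals behind each sample. The groups follow the source names of the 2 samples.

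The authors deposited 1 signal intensity per probe set and array, on a linear scale, computed with MAS5 per the submitters' processing notes. MAS5 subtracts a local background, combines the probe pairs of a probe set with a robust mean and multiplies each array by 1 factor. The MAS5 version and the scaling settings are not given in the sources used here. In the deposited intensities the 2% trimmed mean of the first 100 listed probe sets was 2000.0 on both arrays, while that of all 45037 probe sets was 383 on the stimulated array and 340 on the triptolide array. The arrays therefore appear to have been scaled on those 100 probe sets, so the level of all other probe sets rests on the assumption that these did not change. Detection calls and the array's own control probe sets (spike-ins, and 5′ and 3′ probe sets of Actb and Gapdh) were not used here, so labelling efficiency and RNA integrity were not compared.

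Probe sets were named through the platform annotation. Of the 45037 probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none, and only the first kind entered the gene comparison. For 34741 probe sets the Entrez gene number was found in the RefSeq gene table of assembly GRCm38.p6, and the symbol was taken from there, changed or not. That table was used for names only, so no coordinates are given. Each of the 18193 genes was represented by its probe set with the highest mean log2 signal over both arrays.

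Background was set from genes not expected in T cells. The 95th percentile of the 87 probe sets of olfactory, vomeronasal, taste and trace amine receptor genes was 107 on the stimulated array and 118 on the triptolide array, and the higher value, 118, served as a common floor. Signals under the floor were set to it before log2 ratios were taken. A gene was called detected with a signal above the floor on at least 1 array and measured with signals above it on both. Where 1 side lay at the floor, the fold is a lower bound and is written "at least".

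With 1 array per group no test between the groups is possible, so no p-value, standard error or SD across replicates is given. Genes were counted by a fixed rule of size (at least 2-fold on floored signals). The spread between probe sets of the same gene served as a guide to technical precision. It covers probe behaviour and transcript variants but not the variation between cultures or animals. For 39 gene lists, the median log2 ratio of the detected members was ranked among 10000 random lists of as many detected genes, matched on mean signal in 20 bins. This percentile describes these 2 arrays only. It was given for the 34 lists with at least 5 detected members, and a list is said to stand apart where it lies outside the central 95% of random lists. Intervals of a list's median come from 10000 bootstrap draws of its members.

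The lists, the floor, the fold rule and the rule for naming genes were fixed before the data were examined. Named were the 12 genes with the highest and the 12 with the lowest ratio among genes measured on both arrays, with a brighter signal of at least 4 times the floor and with all measured probe sets going the same way. To these came the 6 brightest genes per direction that were at the floor on the other array with a bound of at least 4-fold, the 2 highest and 2 lowest members of each list, and a short set of genes needed to describe the lists. Other genes named below were picked from the lists after their values were seen.

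The calculation was tested on simulated data for the comparison of the triptolide with the stimulated array, with noise of 0.39 (log2) per probe set, the robust SD between probe sets of the same gene. Their plain SD was 0.49, so the shares called hold for the smaller noise. The changed genes were drawn only from genes with a mean signal of at least 4 times the floor, so their shares do not cover dimmer genes. Among 66 genes changed 4-fold, 98.5% were called at least 2-fold in the right direction, as were 47.1% of 68 genes changed exactly 2-fold. Of 10062 unchanged genes, 0.954% were called. These included dim genes at the same noise, which was estimated from probe sets above the floor on both arrays. Larger noise in dim genes is therefore not covered by that share. With no gene changed and independent noise in each probe set, 5.63% of 320 list percentiles fell outside the central 95%. Alternatives were 3 other scalings, 2 other floors or none, a pseudocount, another choice of probe sets per gene, limits to brighter genes or to agreeing probe sets, and other fold thresholds. Scaling on hybridisation spike-ins was planned and not run, for want of those probe sets. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.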

Results

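The series asked which genes triptolide affects in activated T cells. Triptolide is a plant diterpenoid with immunosuppressive activity that binds the XPB subunit (Ercc3) of the general transcription factor TFIIH. T cells were stimulated through the T cell receptor and the costimulatory receptor CD28, with or without triptolide at 50 ng/ml, and each condition was measured on 1 array. All values below are MAS5 signals of these 2 arrays, without replicates. The median signal over 45037 probe sets was 95.5 on the stimulated array and 87.6 on the triptolide array, and 44.9% and 42.2% of the probe sets lay above the background floor of 118. Probe sets of chemosensory receptor genes, taken as background, had median signals of 16.7 and 25.6. Log2 signals of the 16687 probe sets above the floor on both arrays correlated across probe sets with r = 0.895, a description of these arrays in which genes are not independent replicates.

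With triptolide, p53 target genes were higher as a list (11 of 24 detected members at least 2-fold higher and 1 lower). The gene for the largest RNA polymerase II subunit was higher too. The inducible heat shock genes Hspa1a and Hspa1b, the metallothioneins Mt1 and Mt2, and genes of glycolysis and glucose uptake as a list were lower. The effector genes Il2, Ifng, Il17a, Gzma and Gzmb were also lower. Of 26 detected T cell identity genes, 11 were at least 2-fold lower and 22 had a log2 ratio below 0. The effector genes Tnf, Ccl5, Xcl1 and Ctsc were higher. Of 10968 detected genes, 618 were at least 2-fold higher with triptolide and 1370 at least 2-fold lower, and 8980 lay within 2-fold. At least 4-fold differences were seen for 85 higher and 149 lower genes. In 153 of the higher and 239 of the lower genes the fold is a lower bound, because 1 side was at the floor. The median log2 ratio of all detected genes was -0.16, and ratios are best read against that shift. Lower genes made up 68.9% of the 2-fold differences as deposited and 62.1% when scaled on housekeeping genes. At the ends of the interval of the housekeeping median that share was 13.6% and 81.7%, so the direction of the excess depends on the scaling. The share was 53.6% after centring both arrays on their median and 50.9% after quantile normalization, 2 settings that even out the arrays by construction.

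Probe sets of one gene gave a view of technical precision. In 3733 genes with at least 2 measured probe sets, the log2 ratios of the brightest pair correlated with r = 0.60 across genes, and the SD between them was 0.49 per probe set (log2), against an SD of 0.75 for the ratios themselves. Over all 3733 genes, whatever their fold, the second probe set went the same way in 2688 (72.0%). It did so in 176 of 201 genes (87.6%) whose brightest probe set was at least 2-fold higher, and in 416 of 464 (89.7%) that were at least 2-fold lower. It was itself at least 2-fold in 93 and 242 of them. A single gene near 2-fold is thus weakly supported. The genes named first below lie well beyond this spread on their brightest probe sets, but they were picked as the most extreme ratios. Several of them, such as Dhx40, Id1, Tex14 and Ctla4, have a single probe set. Lying beyond this spread does not speak for a difference between cultures.

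**Figure D1:**
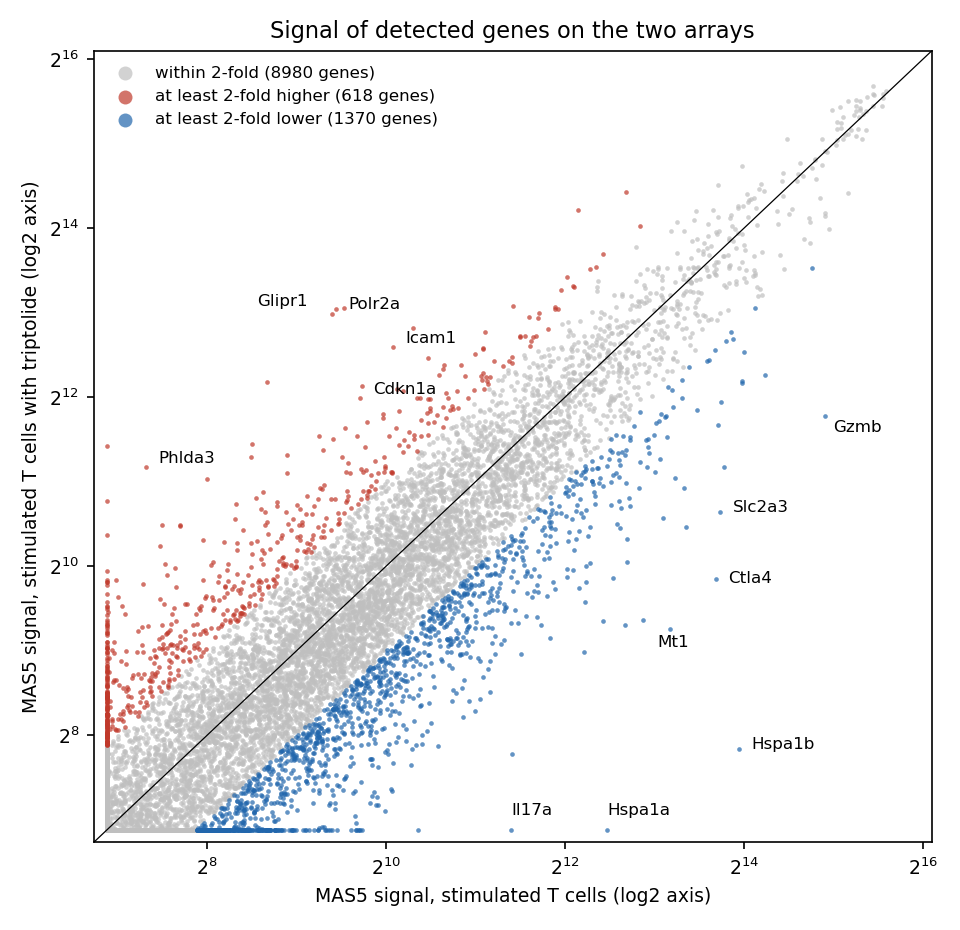
MAS5 signal of each detected gene in stimulated T cells (x axis) and in stimulated T cells with triptolide (y axis), both on log2 axes, with signals under the floor of 118 drawn at the floor and the line of equality in black. Of the coloured genes, 618 lie at least 2-fold above and 1370 at least 2-fold below the line, with Polr2a and Phlda3 among the highest and Hspa1b and Hspa1a farthest below.

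The highest ratio among genes measured on both arrays was that of Phlda3, a p53-induced inhibitor of AKT signalling, with a signal of 159.8 without and 2306 with triptolide (14.4-fold, on its single probe set). Polr2a, which encodes the largest subunit of RNA polymerase II, followed at 12.1-fold (697 to 8439.6), and its dimmer second probe set was under the floor without triptolide and at least 5.10-fold higher with it. Glipr1, a p53-inducible gene, had a log2 ratio of 3.58 on its brightest probe set (675 to 8088) and of 0.45 on the other. Dhx40 was 11.5-fold higher, Pdrg1 11.4-fold, Tcta 8.18-fold and Rprd1a 7.91-fold. The other probe sets measured on both arrays were 6.66-fold higher for Pdrg1 and 3.18-fold higher for Rprd1a. A further Rprd1a probe set, under the floor with triptolide, went the other way (137.5 to 102.4). Id1, an inhibitor of basic helix-loop-helix transcription factors, was 7.68-fold higher, and Tex14, Mtch1, Lrrc51 and Blcap were 7.24-, 6.96-, 6.88- and 6.87-fold higher. Genes under the floor without triptolide included Colec11 (at least 23.2-fold), the cardiac troponin gene Tnnt2 (at least 14.7-fold, with all 3 probe sets at the floor without triptolide), Tspoap1 (at least 11.2-fold), Gm1070 (at least 7.73-fold) and Gm5617 (at least 7.59-fold). D130037M23Rik was at least 8.33-fold higher on its brightest probe set, under the floor without triptolide, and 3.29-fold higher on the other, measured on both arrays (138.5 to 455).

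The lowest ratio was that of Hspa1b, an inducible HSP70 gene, with a signal of 15768 without and 229 with triptolide (68.8-fold lower), and its 3 probe sets gave log2 ratios between -6.10 and -5.23. The near-identical Hspa1a was at least 47.9-fold lower, and the probes may not tell the 2 copies apart. The metal-binding metallothioneins Mt1 and Mt2 were 15.0-fold and 10.3-fold lower, and the second probe set of Mt1, under the floor with triptolide, was at least 3.41-fold lower. Ctla4, an inhibitory receptor induced by activation, was 14.2-fold lower (13133 to 922). Tgm2 was 12.4-fold lower, the snoRNA host transcript Zfas1 11.4-fold, the chemokine receptor gene Cxcr4 8.37-fold, Gzmb 8.67-fold and Plcxd1 7.35-fold. The glycolytic gene Aldoc was 9.38-fold lower on its brightest probe set, its second being dim (136.5 without triptolide) and under the floor with it, and the glucose transporters Slc2a3 and Slc2a1 were 8.49-fold and 7.40-fold lower. Among genes under the floor with triptolide, Il17a was at least 22.8-fold lower (2696 to 67.0), Bend5 at least 11.1-fold, the chemokine Cxcl2 at least 7.18-fold, Ciart at least 7.08-fold and Coq7 at least 7.02-fold.

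Of the 34 ranked gene lists, 10 lay below and 4 above the central 95% of matched random lists. Chance would place 1.7 in all if genes varied independently. Genes of one list can move together between any 2 cultures, which the random lists do not allow for. Several lists share members, so they do not count as independent.

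The p53 targets stood apart most clearly upwards. Of 24 detected members, 11 were at least 2-fold higher and 1 was at least 2-fold lower, with a median log2 ratio of 0.71 (95% interval over members 0.45 to 1.51) that lay above all 10000 random lists. Besides Phlda3, Plk2 was at least 7.43-fold higher, the BH3-only gene Pmaip1 5.30-fold and the cell cycle inhibitor Cdkn1a 4.86-fold (838 to 4072). Trp53inp1, Ccng1, Zmat3 and Aen were between 2.85- and 3.31-fold higher. Mdm2, the p53-induced p53 ubiquitin ligase, had a log2 ratio of -0.07. Ddit4, a stress-induced mTOR inhibitor that also responds to other pathways, was 4.17-fold lower, and Perp had a log2 ratio of -0.73. Proapoptotic BCL2 genes and caspases did not stand apart (17 detected, median 0.21, percentile 96.1), with Pmaip1 higher and Casp6 4.63-fold lower, while Bmf was at least 5.03-fold higher on one probe set and had a log2 ratio of -0.57 on another. Antiapoptotic BCL2 and IAP genes did not stand apart either (10 detected, percentile 71.5), except upwards among genes with a brighter or a mean signal of at least 4 times the floor (percentiles 97.9 and 98.1). Of them, Mcl1 was 3.07-fold lower (11359 to 3698, all 6 probe sets lower) and Bcl2 2.74-fold lower, while Bcl2l1 had a log2 ratio of 0.87 and Birc5 was 2.02-fold higher.

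Genes of glycolysis and glucose uptake were lower as a group: 9 of 20 detected members were at least 2-fold lower and none was at least 2-fold higher, and the median of -0.94 (95% interval -1.51 to -0.70) lay below all 10000 random lists. Besides Aldoc, Slc2a3 and Slc2a1, these were the phosphofructokinase regulator Pfkfb3 (4.86-fold), the lactate transporter Slc16a3 (3.79-fold), Ldhb (2.88-fold), hexokinase Hk2 (2.83-fold), Pfkl (2.72-fold) and Pdk1 (2.06-fold). Pgam1 had a log2 ratio of 0.06 and Slc16a1 of 0.90. Nuclear-encoded oxidative phosphorylation genes did not stand apart (45 detected, median 0.04, percentile 90.3), nor did ribosomal proteins (43 detected, median 0.04, mean -0.0070, percentile 89.9), the proteasome (31 detected, median -0.01, percentile 75.7) or NRF2 targets (12 detected, median -0.13, percentile 54.0). Cholesterol synthesis genes had a median of -0.70 (19 detected, 5 at least 2-fold lower, percentile 0.74), led by Fdps at 4.16-fold and Dhcr7 at 3.29-fold lower. That list no longer stood apart in 3 of 11 alternatives, with percentiles up to 7.24 (without probe sets shared between transcripts).

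In the heat shock list 4 of 21 detected members were at least 2-fold lower and none higher (median -0.52, 95% interval -0.72 to -0.15, percentile 0.32). These were Hspa1b, Hspa1a, the small heat shock protein gene Hspb1 (4.55-fold) and the HSP70 cochaperone gene Dnajb1 (2.02-fold), while Dnajb4 and Hsp90aa1 had log2 ratios of 0.41 and 0.34. Without shared probe sets the percentile was 4.31. In the list of ER stress and integrated stress response genes, 8 of 26 were at least 2-fold lower and 1 higher (median -0.60, percentile 1.11, or 3.09 without shared probe sets). The lower ones included the amino acid synthesis genes Asns (6.19-fold), Phgdh (3.55-fold) and Psat1 (3.11-fold), and Xbp1 (3.47-fold). The ER chaperone gene Hspa5 had a log2 ratio of 0.14, and Dnajb9 was 2.57-fold higher.

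**Figure D2:**
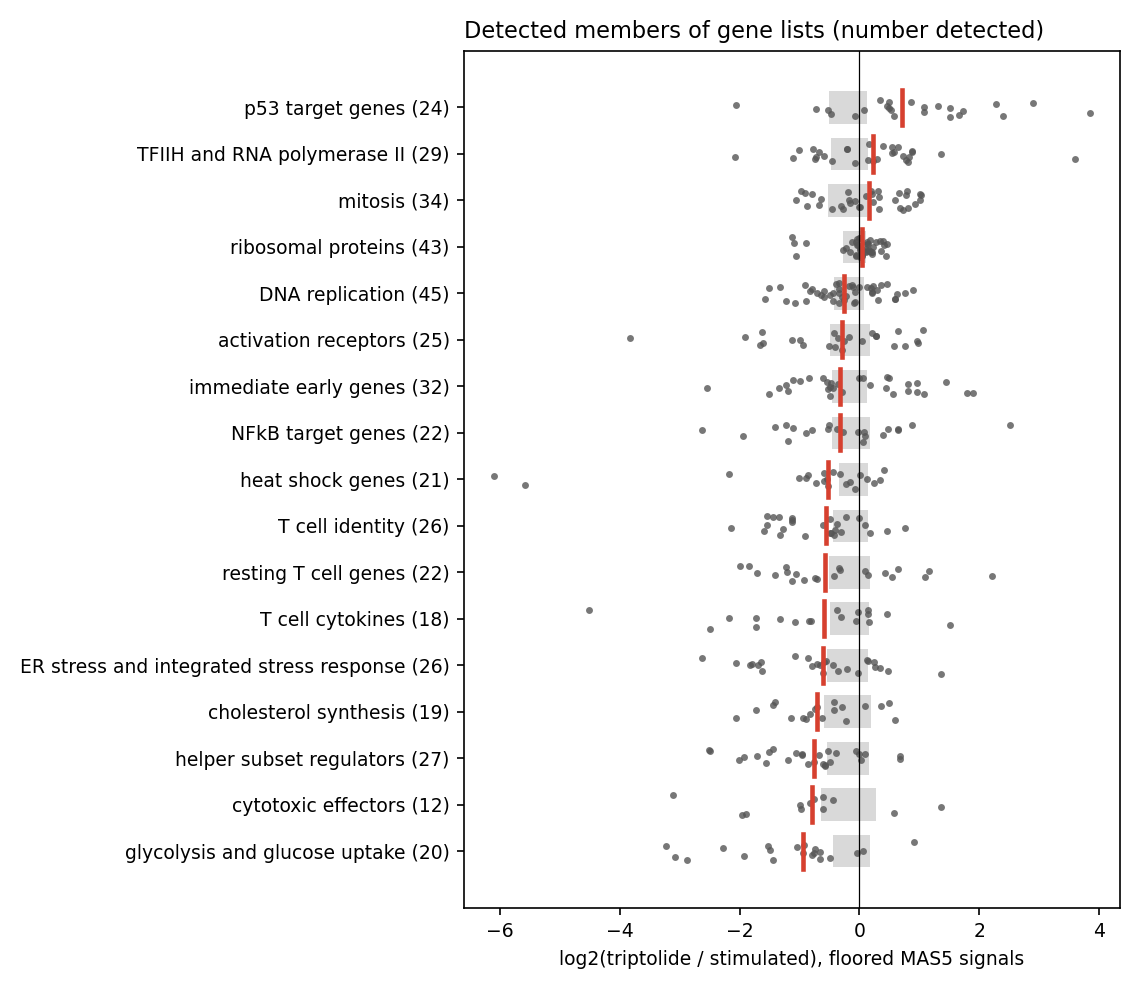
Log2 ratio of triptolide to stimulated signal (x axis) for the detected members of 17 gene lists (y axis, number detected in brackets), as grey points with the list median as a red bar and the central 95% of medians of 10000 matched random lists as a grey band. The p53 target median of 0.71 lies right of its band and the glycolysis median of -0.94 lies left of its band, while immediate early and NFκB target medians fall within theirs.

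Of 18 detected cytokine genes, 7 were at least 2-fold lower and 1 at least 2-fold higher (median -0.59, 95% interval -1.53 to 0.05, percentile 0.58). Besides Il17a, the T cell growth factor Il2 was at least 5.61-fold lower (665 to 113, and 1953 to 1329.7 on a probe set shared with Ntan1), the macrophage-activating cytokine Ifng 4.50-fold (2124 to 472), Osm 3.32-fold and Lif 3.30-fold lower. Tnf went the other way and was 2.86-fold higher (398 to 1139.8), and Tnfsf14 had a log2 ratio of 0.47. Chemokine genes were mixed (6 detected, percentile 96.1), with Ccl5 2.75-fold and Xcl1 at least 3.83-fold higher and Cxcl10 3.20-fold lower. Among cytotoxic effectors, 3 of 12 were at least 2-fold lower and 1 higher (median -0.79, 95% interval -1.44 to -0.52, percentile 0.50), with Gzmb at 8.67-fold, Gzma at 3.91-fold and Serpinb6b at 3.73-fold lower, and the protease gene Ctsc 2.56-fold higher.

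Activation receptors did not stand apart as a list (25 detected, 6 at least 2-fold lower, 1 higher, median -0.29, percentile 19.9). Ctla4 and the IL-2 receptor gene Il2rb (3.75-fold) were lowest, while Cd44 had a log2 ratio of 0.97. Cd80 was 2.08-fold higher near the floor on its brightest probe set (129 to 269). On another probe set, under the floor with triptolide, Cd80 went the other way (173.4 to 115.5). The early marker Cd69 had a log2 ratio of 0.27. For Il2ra, the high-affinity IL-2 receptor chain, the 2 probe sets disagreed, with log2 ratios of -0.26 and 2.26, so no direction is given.

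Immediate early genes went both ways (32 detected, 4 at least 2-fold higher and 6 lower, median -0.32, percentile 16.3), with a median of 0.03 without shared probe sets and of -0.48 (percentile 2.37) among genes with a mean signal of at least 4 times the floor. Ier3 was 5.82-fold lower, Klf6 2.86-fold, Junb 2.29-fold and Myc 2.16-fold lower. The ERK phosphatase Dusp6 was 3.75-fold and Nr4a2 2.72-fold higher. Egr2 was 3.48-fold higher on its brightest probe set and had a log2 ratio of 0.50 on the other, near the floor (118.6 to 168.1). Fos and Jun had log2 ratios of 0.46 and -0.44. NFκB target genes were likewise within the range of random lists (22 detected, 6 at least 2-fold lower, 1 higher, median -0.32, percentile 13.95). Bcl3 was 6.15-fold, Rel 3.83-fold and Tnfaip3 2.66-fold lower, Nfkbia had a log2 ratio of -0.52 (5 probe sets between -0.82 and -0.10), and the adhesion molecule Icam1 was 5.72-fold higher (1081 to 6179). The NFAT and calcium list (13 detected, percentile 10.2) included Plcg1 with a log2 ratio of -1.73 and Orai1 with 0.99.

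T cell identity genes were lower as a list: 11 of 26 detected members were at least 2-fold lower and none higher (median -0.55, 95% interval -1.20 to -0.40, percentile 0.64). Runx3 was 4.45-fold lower, Cd28 2.92-fold, Bcl11b 2.92-fold and Cd4 2.43-fold lower. Cd8a was 3.03-fold lower on its brightest probe set, with 1 of 5 probe sets slightly higher (0.17). The T cell receptor subunit Cd3e had a log2 ratio of 0.46 and Cd6 of 0.76. Regulators of helper subsets were lower too, 10 of 27 by at least 2-fold and none higher (median -0.75, 95% interval -1.19 to -0.53, percentile 0.065), led by Ikzf3 at 5.72-fold, Id3 at 5.66-fold, Bhlhe40 at 4.04-fold and Ahr at 3.81-fold. Genes typical of resting T cells had a median of -0.57 (22 detected, 8 lower and 3 higher, percentile 1.12), with Klf2 (3175 to 794) and Il7r (3.60-fold) lower and the antiproliferative gene Tob1 4.64-fold higher. That list no longer stood apart in 4 of 11 alternatives, with percentiles up to 10.3.

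Markers of other cell types that a T cell preparation could hold were compared beside these. B cell markers had a median of -0.71 (13 detected, 4 at least 2-fold lower, 1 higher, percentile 0.835), with H2-Ab1 2.97-fold lower, Blnk at least 2.58-fold lower and Ighm at a log2 ratio of -0.95, but Cd79a at 0.95 and Cd74 2.00-fold higher. The list did not stand apart in 5 of 11 alternatives, with percentiles up to 4.20. Myeloid markers did not stand apart (12 of 20 detected, median 0.23, percentile 92.7), with Lyz2 at signals of 72.2 and 259.5 and the brightest member, Ctss, at a log2 ratio of 0.47. Natural killer cell markers (6 detected, percentile 68.8), neutrophil markers (5 detected, percentile 83.6) and stromal markers (5 detected, percentile 46.2) did not stand apart. Dendritic cell and thymocyte markers each had 4 detected members, platelet markers 2 and erythroid markers 1, too few to rank. Both platelet markers were higher, Gp5 2.92-fold (296 to 862) and Itga2b 2.13-fold (191 to 407).

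Among genes of the transcription machinery that triptolide acts on, 2 of 29 detected members were at least 2-fold higher and 3 lower, with a median of 0.24 (95% interval -0.22 to 0.58, percentile 99.4, or 96.6 with the median over all probe sets of a gene). Polr2a and the P-TEFb inhibitor gene Hexim1 (2.57-fold) were higher, Ercc3 had a log2 ratio of 0.81, and the TFIIH kinase module genes Mnat1 and Ccnh were 4.23-fold and 2.16-fold lower. The third component of that module, Cdk7, had a log2 ratio of -0.21.

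Proliferation genes stayed mostly within 2-fold. Of 45 detected DNA replication genes, 5 were at least 2-fold lower, led by Pole2 and Pold2 with log2 ratios of -1.58 and -1.52, and none was higher (median -0.26, percentile 27.2). Mitosis genes had a median of 0.16 (34 detected, 3 higher, 1 lower, percentile 98.2), which stood apart in 1 of 11 alternatives only. G1 cyclins and CDK inhibitors (12 detected, percentile 38.6) held Cdkn1a as their highest and Cdkn2d, with a log2 ratio of -1.74, as their lowest member. Ribosome biogenesis genes had a median of -0.33 (28 detected, percentile 10.4), and interferon response genes of -0.17 (27 detected, percentile 48.7). Histone genes, a list that holds linker histone genes beside core ones, went both ways (7 detected, median 0.48, mean -0.12, percentile 98.2). H2bc21 was 5.10-fold higher, and the linker histone gene H1f4 was at least 4.09-fold lower. The list no longer stood apart upwards in 4 of 11 alternatives. In 1 of these, without shared probe sets, it stood apart downwards (median -1.52, percentile 0.26). Of the mitochondrially encoded genes 1, ND5, had a probe set of its own and was 3.36-fold higher. Housekeeping genes had a median of -0.08 (16 detected, percentile 48.0). Actb had log2 ratios of -0.10 and 0.79 on its 2 probe sets. Gapdh, present only on 3 probe sets shared with other gene symbols, had signals of 42949 and 39519 on the brightest, 847 and 227 on the next and 525 and 364 on the dimmest. Tubb5 was 3.44-fold lower on its brightest probe set and had a log2 ratio of 0.87 on the other.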

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

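The alternatives were planned before the data were examined, except the limits to bright genes (by the brighter or the mean signal) and to several agreeing probe sets, which were chosen after seeing them. The counts of higher and lower genes (618 and 1370) were 2111 and 2966 with the floor at the median of the receptor probe sets, and 2863 and 3661 with none, since more dim genes then enter. They were 189 and 387 at 3-fold, 1470 and 2955 at 1.5-fold, 162 and 391 in genes with several probe sets that go the same way, and 280 and 702 in genes with a mean signal of at least 4 times the floor. Quantile normalization gave 867 higher and 899 lower genes. Of 88 recomputed medians of the 8 main lists, 85 stayed within the interval over members. The others were T cell identity at -0.38 after median centring, and DNA replication at -0.0771 after median centring and -0.0276 after quantile normalization. The p53, glycolysis, T cell identity, cytokine, cytotoxic and helper regulator lists stood apart in all 11 alternatives. The mitosis median turned to -0.0015 among genes with a brighter signal of at least 4 times the floor and to -0.0853 by the mean signal. The histone median turned to -1.52 without shared probe sets. Among lists that had not stood apart, medians also changed sign, such as immediate early genes (0.03) and ribosomal proteins (-0.24) without shared probe sets and neutrophil markers (-0.49) with no floor. Without shared probe sets Atp5c1, Tubb5 and Lyz1 turned to 0.24, 0.87 and -0.41. Median centring removed a shift of -0.18 (log2) between the arrays, and scaling on housekeeping genes -0.08. Of 113 named genes with at least 2-fold, 82 kept that size and direction in every alternative that gave a value; the cause of the remaining differences was not tested. No paired analysis was possible because each group has 1 array. Scaling on spike-in probe sets, which were not analysed here, was not run. Both the single array per group and the scatter between probe sets limit the precision.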

Other observations

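Gene families were also scanned by symbol, with families chosen after the main lists had been seen. Some of their members, such as Ccr7 and Il2rb, are also in the lists above, so the families are not independent of them. Of 20 families, 3 lay below and 2 above the central 95% of matched random lists, where chance would place 1 if genes varied independently. Chemokine receptor genes were lowest (10 detected, 6 at least 2-fold lower, none higher, median -1.20, percentile 0.02). Besides Cxcr4, Ccr8 was at least 4.64-fold lower, Cxcr6 4.14-fold, Cxcr5 2.43-fold, Ccr7 2.35-fold and Ccr2 at least 2.25-fold lower on its brightest probe set (log2 ratio -0.71 on the one measured on both arrays). Aminoacyl-tRNA synthetase genes had a median of -0.53 (31 detected, 7 at least 2-fold lower, none higher, percentile 1.30), with Cars 4.28-fold and Sars 2.55-fold lower, while Kars and Hars had log2 ratios of 0.17 and 0.18. Genes of enzymes that add or remove histone methyl and acetyl groups (symbols starting Kmt, Setd, Kdm, Kat or Hdac) had a median of -0.48 (50 detected, 10 lower, 4 higher, percentile 1.40), with Kat5 5.47-fold and Hdac7 4.16-fold lower and Kdm2a 3.42-fold higher. The 2 above were cyclins (20 detected, 2 at least 2-fold higher, 3 lower, median 0.20, percentile 97.8) and interleukin receptor and related genes (23 detected, 1 higher, 6 lower, median 0.26, mean -0.16, percentile 99.0). In the latter, Il15ra was 4.78-fold higher and Il2rb 3.75-fold lower, and several higher members were under the floor without triptolide. The 15 other families did not stand apart, among them solute carriers (197 detected, percentile 68.0), initiation factors (45 detected, percentile 39.4) and mitochondrial ribosomal proteins (76 detected, percentile 82.0). Of the 9160 probe sets without a gene name, 134 were at least 2-fold higher and 286 at least 2-fold lower.

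Explanations for 3 patterns and hypotheses on 2 more were set against the data. The patterns were themselves picked from these data, so each test is a follow-up and not an independent prediction. The tests of scaling, of dim signals and of overall activation were chosen after the values they use were seen. The others were written before they were run, but after their pattern was seen. All come from the same pair of arrays, so a difference between the 2 cultures other than triptolide (animals, cell density, labelling) stays open for each of them.

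The p53 targets were higher with triptolide as a list, with 11 of 24 detected members at least 2-fold higher and 5 below 0. A single scaling factor as the whole cause is argued against, since it would shift all genes alike. The lower end of the interval of the list's median lay 0.62 (log2) above the median of all detected genes. The list was already known to stand apart, so this test adds little beyond its rank. Scaled signals are relative to the other transcripts, so a change in total mRNA per cell is not covered. Dim signals are argued against too, since the 14 members with a mean signal over both arrays of at least 4 times the floor ranked at percentile 100 of their matched lists. A member can pass this limit through its triptolide signal, as Phlda3 did (159.8 without and 2306 with triptolide). The limit raised the list median from 0.71 to 1.41, so the change itself helped to choose the members. A second list of p53 targets that shares no gene with the first ranked at percentile 99.99 (25 detected, 7 at least 2-fold higher, 1 lower, 95% interval of the median -0.06 to 0.99), with Psrc1 3.39-fold and Slc19a2 3.34-fold higher. Higher p53 activity with triptolide is therefore a candidate explanation, although Mdm2 stayed at -0.07, and neither p53 protein nor survival of the cells was measured here.

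Glycolysis genes were lower with triptolide as a list, with 9 of 20 detected members at least 2-fold lower and 2 above 0. A single scaling factor as the whole cause is argued against, since it would shift all genes alike. The upper end of the interval of the list's median lay -0.54 (log2) from the median of all detected genes. Here too the test adds little beyond the list's rank. HIF1 target genes outside glycolysis, a list with no member in the glycolysis list, ranked at percentile 0.01 (25 detected, 11 at least 2-fold lower, none higher), with the HIF prolyl hydroxylase genes Egln1 and Egln3 4.48-fold and 3.33-fold, Bnip3 4.09-fold and Vegfa 3.50-fold lower. Lower HIF1 target expression is thus a candidate explanation, but HIF1 protein was not measured and other regulators of these genes were not tested. Hif1a had a log2 ratio of -0.79, but it is itself a member of the glycolysis list and adds no separate support. Lower activation as a whole remains open, since the activation receptor list ranked at percentile 19.9, between the bounds set for the test. The test also required Slc2a1, Slc2a3 and Hk2 to fall no further than the average of the lowest activation receptors, and this was not met. Slc2a3 (log2 ratio -3.09) and Slc2a1 (-2.89) fell further than every detected receptor but Ctla4 (-3.83), the next being Il2rb (-1.91).

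More genes were at least 2-fold lower than higher. Whether scaling accounts for the excess remains open: lower genes made up 62.05% when scaled on housekeeping genes, but 13.6% and 81.7% at the ends of the interval of their median, and centring on the median evens out the split by construction. Dim signals are argued against, since lower genes made up 71.5% of the differences among genes with a mean signal of at least 4 times the floor. A loss of short-lived mRNAs under reduced transcription remains open: Zfp zinc finger genes, whose mRNAs are known to turn over fast, ranked at percentile 12.2 (236 detected, 27 at least 2-fold lower, 9 higher).

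Zfas1, Taf1d and Rabggtb, which host snoRNAs in their introns, were 11.4-fold, 6.49-fold and 6.27-fold lower, with the 5 measured probe sets of Taf1d between -2.70 and -0.24 (log2). The hypothesis that such hosts were lower as a class was tested on 15 others, which ranked at percentile 0.37 (6 at least 2-fold lower, none higher), with Snhg5 4.55-fold, Snhg6 4.23-fold, Snhg12 4.02-fold and Gas5 3.47-fold lower. The highest members were Prrc2a and Tnpo2, with log2 ratios of 0.39 and 0.17. For Mt1 and Mt2, a lower response to zinc was tested on zinc transporters and Mtf1, which ranked at percentile 58.4 (18 detected, 3 lower, 2 higher). These members went both ways (95% interval of the median -0.57 to 0.44), so the test does not decide.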
